A study of Bos taurus with 13 samples.

How the data were processed

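The series holds 13 two-colour hybridisations to a bovine mammary cDNA microarray. 8 arrays set 1 tissue each against total RNA of a reference cell line named BovMac (adipose tissue, adrenal tissue, ileum, liver, lymph tissue, spleen, thymus and the mammary gland of a 136 kg prepubertal Holstein heifer). 2 arrays set lactating mammary gland against the gland of a prepubertal heifer of 136 kg (array 1) or 227 kg (array 2). 1 array set the gland of a 136 kg prepubertal heifer against that of a 310 kg postpubertal heifer. 2 arrays set the reference against itself, to measure the rate of false positives per the labels. 9 groups had 1 array and 2 groups had 2. The label of reference against reference array 1 spells the cell line BovMav. A keyword of lactating array 2 reads post-pubertal where its title and channel read prepubertal, and the title was followed.

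The deposited table gave 1 log ratio per spot, with 3888 spots per array. The authors' background correction, normalization, base of the logarithm, order of the channels and centring are not given in the sources used here. Array medians of the deposited log ratios, over spots other than exact 0, lay between -0.0997 and 0.0304. The sizes rule out a base of 10 but leave base 2 and the natural log open. A change of 1 log unit is therefore 2-fold in base 2 and 2.72-fold in the natural log, and no value was converted. The labels name the RNA of each channel but not the dyes. The lists fixed for reading the direction on the tissue arrays held 3 measured hepatocyte genes, whose signs differed, and 0 genes of the adrenal, thymus, ileum and adipose lists, so direction stayed unsettled and signs are those of the deposited ratio. On the arrays with lactating gland, the positive side is called the casein side, and the negative side the opposite side. The casein side is likely the one where RNA was more abundant in lactating gland, on the basis of the milk secretion list fixed in advance. The plan gave a direction only if the tissue lists and the milk secretion list picked the same order of channels. The tissue lists could not, so this reading departs from the plan. Lactating RNA was in channel 1 of its arrays, and tissue RNA in channel 2 of the tissue arrays. If all arrays shared 1 order of channels, a positive tissue ratio would then be the side of the reference. Whether they did is not stated.

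Rows ran in 1296 clones of 3 consecutive spots, and 0 clones mixed accessions. The platform annotation named 1 gene for 2538 spots, several for 30 and none for 1320. Symbols were looked up by gene identifier in the RefSeq table of assembly ARS-UCD2.0, which held 700 of the 703 genes kept, and 0 symbols changed. No coordinates were used. A run of 144 unannotated spots stood at exact 0 for 59.7% to 100% of its spots on each array, so an exact 0, found for 124 to 373 spots per array, was treated as no ratio. That choice, and the filters that follow, were made after the data were seen. Each array's log ratios were centred on the median, spots of 1 accession (or of 1 unannotated clone) were averaged into a feature with a minimum of 2 spots, and 1179 of 1234 features with a value on at least 7 arrays were kept. Of these, 782 named 1 gene. A gene's value was the mean of its features. The actin gene ACTB had 150 spots. GAPDH, which the labels say was left off the array for the reference against reference hybridisations, was named by 0 spots. Intensities were not used here, so no array could be adjusted for brightness, and the number of arrays limits the precision.

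For arrays without a replicate, features were counted at 1 log unit or more from 0, beside the same count on the reference against reference arrays, and no p-value was made. A feature stood apart in a tissue when it lay at least 1 unit above the highest, or below the lowest, of the other tissues. Lists with at least 5 genes were placed among 10000 random lists matched on deciles of the mean over the other tissue arrays. For the lactating arrays, and for the reference against reference arrays, the mean of the 2 arrays was tested against 0, two-sided, with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) and Benjamini-Hochberg adjustment at 0.05. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. Correlations were computed across features, which are not independent replicates. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 did the rest, and shares carry 95% Wilson intervals that cover counting error only.

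Of 26 lists fixed before the data were examined, 8 had 0 measured genes (adipocyte, adrenal, ileum epithelium, T cell, B cell, macrophage, blood and translation factor lists), 13 had 1 to 4 and 5 were tested. Genes were named by a rule written before the data were examined: on the lactating arrays the 15 highest and 15 lowest past adjusted p 0.05 on the same side of both arrays, ranked by the smaller of the 2 values. In the tissues it took the 15 largest margins above and 5 below for mammary gland and the 4 largest margins above for each other tissue. It also took up to 4 members of each list per comparison, all milk protein genes, GAPDH and the 4 features with the largest mean on the reference against reference arrays. The rule also covered the postpubertal array. No gene was named from that array, as an exception made after its spots were seen not to agree within clones, and its gene lists were left out for the same reason.

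The tests were tried on simulated data. With 200 of 1167 features changed in each of 20 simulated pairs of arrays, drawn with the fitted spread of the lactating comparison, limma found 98.8% of changes of 1 unit and 100% of changes of 2 units, with 13.55 unchanged features called per draw. The draws took their spread from limma's own fit, so the shares found need not carry over to the real arrays. Without any change, 10 of 20 draws gave at least 1 call, with a mean of 1.55 calls. Calls without any change were thus more frequent than the limit on adjusted p should allow. The adjusted p-values of the lactating comparison may therefore be too small. In simulated lists on 703 genes, 40 of 40 lists shifted by 1 unit lay above the 95th percentile, and of 40 unchanged lists, drawn at random, 6 did and 2 lay below the 5th. Alternatives covered centring, scaling, the size rule, the features used, the reference arrays in the fit, the test and each array left out. Others were added after the data were seen.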

Results

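The arrays asked which genes printed on a mammary cDNA platform differ between bovine tissues, and between stages of mammary development. 1134 to 1178 of the 1179 features had a value on each array. The mean Spearman rho between the 3 spots of a clone was 0.52 to 0.84 on the 10 arrays of tissues and lactating gland, 0.58 and 0.11 on the reference against reference arrays 1 and 2, and 0.06 on the postpubertal array. Values are log ratios of unstated base, with the SD over spots where 1 array was available and the SD over arrays (n = 2) for the lactating comparison.

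In the main limma test, the alpha-S1 casein gene, the lipid supply genes ACSS2 and CD36 and a group of genes outside the fixed lists differed between lactating and prepubertal mammary gland. Both arrays held lactating RNA in the same channel, so a dye effect of a clone need not cancel between them. CSN1S1, which encodes alpha-S1 casein, lay at 2.09 ± 0.67 (SD, n = 2) on the casein side, with an adjusted p of 1.36e-06 by limma. CSN2, the gene of beta-casein, lay at 0.77 ± 0.02 (adjusted p = 0.00205, limma). In contrast with the reference against reference arrays, which adds their spread, CSN1S1 lay at 2.13 (adjusted p = 0.0686, limma) and CSN2 at 0.95 (adjusted p = 0.0803, limma). Part of that spread comes from reference against reference array 2, whose spots agreed little within clones (mean rho 0.11). With only the mean of the reference against reference arrays subtracted, at the same sizes, the adjusted p was 4.53e-12 for CSN1S1 and 1.3e-05 for CSN2 by limma. That setting puts the noise of those arrays into the sizes but not into the spread, so its p-values are too small. The other milk proteins did not pass the test. Kappa-casein CSN3 was at 0.41 ± 0.80, with 0.98 on array 1 and -0.16 on array 2. CSN1S2 was at 0.10 ± 0.41, LALBA (alpha-lactalbumin) at 0.47 ± 0.33 with an adjusted p of 0.0647 by limma, and PAEP (beta-lactoglobulin) at 0.47 ± 0.14 with an adjusted p of 0.0505 by limma. The 2 features of PAEP disagreed, at -0.14 ± 0.19 and 1.08 ± 0.47.

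The milk secretion list had 9 measured genes, of which 8 lay on the casein side. The direction of that side was read from this list, so the count shows that its genes lay together, not which way. 2 passed over all genes, and 4 passed when adjusted over the list alone. BTN1A1 (0.29 ± 0.04), LTF (0.19 ± 0.04) and MUC1 (-0.10 ± 0.14) did not pass. The list's median was 0.41, and camera at the preset correlation gave an adjusted p of 0.0318 over 5 lists. The call was lost in camera's other settings, with adjusted p = 0.0566 on the deposited values and 0.156 with 1 feature per gene. Camera with an estimated correlation (0.0 for this list, against the preset 0.01) gave an adjusted p of 0.907. That setting rests on 1 residual degree of freedom with 2 arrays, so it could hardly call any list. Fry gave an adjusted p of 0.0544, of 0.0109 on the deposited values and of 0.0757 with 1 feature per gene.

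Of 6 measured genes of milk fat synthesis, 3 passed, all on the casein side. ACSS2, which makes acetyl-CoA from acetate, lay at 1.30 ± 0.05 (adjusted p = 1.38e-05, limma), as the mean of a feature at 2.41 ± 0.08 and another at 0.18 ± 0.19. CD36, a fatty acid transporter, lay at 1.01 ± 0.22 (adjusted p = 0.000286, limma). GPAM, which starts glycerolipid synthesis, lay at 0.54 with 0.54 and 0.55 on the arrays (adjusted p = 0.0225, limma). In contrast with the reference against reference arrays ACSS2 passed (adjusted p = 0.0283, limma), while CD36 (0.155) and GPAM (0.29) did not. GPAM also lost its call on the deposited values (adjusted p = 0.139) and CD36 without array 2 (0.119). SCD (-0.17 ± 0.61, with features at -0.75 and 0.41), ACLY (-0.05 ± 0.52) and ACSL1 (0.03 ± 0.10) did not pass. The same 3 genes passed when adjusted over the list alone, and the list as a whole did not pass camera (adjusted p = 0.122). Fry gave an adjusted p of 0.115, of 0.193 on the deposited values and of 0.0409 with 1 feature per gene.

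Of the genes named by rule on the casein side, the highest means were those of PLET1 (3.29 ± 0.51), CD47 (3.06 ± 0.83), LASP1 (3.02 ± 0.18) and RSL1D1 (2.96 ± 0.64), each with 3 spots. CD47 encodes a surface protein that restrains phagocytosis, and LASP1 an actin-binding protein. Next were AP2B1 of the clathrin adaptor (2.24 ± 0.56), PCMTD2 (2.24 ± 0.09), CDO1, the cysteine dioxygenase (2.20 ± 0.39), SPTLC1, a subunit of the first enzyme of sphingolipid synthesis (2.18 ± 0.11), EMC2 of the endoplasmic reticulum membrane complex (2.14 ± 0.03) and SSBP2 (1.91 ± 0.30). LGALS9 (1.79 ± 0.27), the acid ceramidase ASAH1 (1.77 ± 0.26), the sialyltransferase ST6GAL1 (1.66 ± 0.04) and the chaperonin subunit CCT5 (1.58 ± 0.02) completed the 15 named. LGALS9 was also at -1.98 on reference against reference array 2, and CD47 had no value there and -1.14 on array 1.

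On the opposite side the sizes were smaller. BUB3, a mitotic checkpoint protein, lay at -1.16 ± 0.61, CD300LG at -0.91 ± 0.44, MFSD14B at -0.87 ± 0.24, NXPE3 at -0.86 ± 0.37, ANXA8L1 at -0.86 ± 0.50 and MRPS35 of the mitochondrial ribosome at -0.76 ± 0.51. NET1 (-0.75 ± 0.50), CD99 (-0.68 ± 0.16), the matrix protein ECM2 (-0.68 ± 0.10), BOLA of class I histocompatibility (-0.66 ± 0.18), ATG12 of autophagy (-0.66 ± 0.39), B4GALT4 (-0.62 ± 0.09), MAP7 (-0.58 ± 0.17), KIF22 (-0.57 ± 0.19) and ALKBH1 (-0.53 ± 0.07) were the rest of the 15. ATG12 lay at -1.14 on reference against reference array 1 as well.

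Other lists moved little as groups. In the secretory pathway list, PDIA3, a disulfide isomerase, passed at 0.94 ± 0.59 and HSP90B1 did not at -0.44 ± 0.22. 1 of 6 genes passed, and 2 did when adjusted over the list alone. The list's median was 0.02, while camera pointed to the opposite side (adjusted p = 0.922) and fry to the casein side (adjusted p = 0.115). Of 11 stroma genes 9 lay on the opposite side, but the 1 that passed, COL5A2, lay on the casein side (0.57 ± 0.06), as also when adjusted over the list alone, and the adjusted p of camera was 0.378. TNC (-0.38 ± 0.12) and POSTN (-0.21 ± 0.15) did not pass. Of 5 proliferation genes 0 passed, also when adjusted over the list alone (adjusted p of camera 0.683), with BIRC5 at -0.37 ± 0.27 and PCNA at -0.11 ± 0.06. The proliferation list had a median of 0.05 and a mean of -0.04. Complement C3 passed at 1.13 ± 0.15 and the leukocyte gene RAC2 at -0.53 ± 0.39. In contrast with the reference against reference arrays the adjusted p was 0.27 for both PDIA3 and COL5A2 and 0.306 for RAC2 by limma, and C3, at -0.88 on reference against reference array 1 and without a value on array 2, lost its call with arrays scaled to the same MAD (0.0739). Neither the epithelial genes ELF5 (-0.09 ± 0.03, with features from -0.41 to 0.30), EPCAM (0.14 ± 0.33) and KRT7 (-0.25 ± 0.33) nor the smooth muscle genes ACTG2 (-0.28 ± 0.47), MYH11 (-0.25 ± 0.47) and TPM1 (0.16 ± 0.31) passed. ACTB was at -0.36 ± 0.08 and did not pass.

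The shorter lists held few genes that passed. TAP1, the peptide transporter of class I presentation, lay at 0.40 ± 0.10 and passed only when adjusted over the list alone, whereas BOLA passed over all genes as well. TGFBR2, a receptor of transforming growth factor beta, lay at 0.42 ± 0.18 and also passed only when adjusted over the list alone, beside FGF2 at -0.24 ± 0.09 and GHR at 0.12 ± 0.15. 0 genes passed, over all genes or adjusted over the list alone, among class II histocompatibility genes (CD74 at -0.17 ± 0.12, BOLA-DRB3 at 0.06 ± 0.24), lactose and nutrient transport (SLC39A8 at -0.27 ± 0.23, PGM1 at 0.20 ± 0.08), endothelium (CAV1 at 0.09 ± 0.14, with features at 0.35 and -0.16, EMCN at -0.02 ± 0.03) and oxidative phosphorylation (ATP5PO at -0.42 ± 0.62, SDHD at -0.18 ± 0.12). The same held for EGR1 (-0.07) and HSPD1 (0.20 ± 0.29) of the immediate early and heat shock list, RPL9 (0.31 ± 0.23) of the ribosomal list and the loading controls HPRT1 (0.05 ± 0.03) and YWHAZ (-0.02 ± 0.07). Of the other members, LCP1 (-0.01 ± 0.07), PTPRC (0.08 ± 0.03), A2M (-0.13 ± 0.83) and FGG (0.04 ± 0.02, with features at -0.25 and 0.33) did not pass.

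In all, limma called 136 of 1167 features, 97 on the casein side and 39 on the opposite side, and 103 of 697 genes. 37 features lay at least 1 unit from 0 on the casein side of both arrays and 0 on the opposite side. The arrays correlated across features with a Pearson r of 0.72 and a Spearman rho of 0.59. Of the 10 list genes that passed, 3 did with arrays scaled to the same MAD. Of the 9 with a value on both reference against reference arrays, 4 did with those arrays sharing the spread and 1 in contrast with them. All 9 did with only their mean subtracted, which leaves their noise out of the spread and is no independent check. The p-values rest mostly on a spread that limma pooled over features (8.452 prior degrees of freedom) or over genes. The fit of genes had 14.5 total degrees of freedom. On the deposited values it had 697, which amounts to 1 common spread for all genes. Simulated pairs of arrays without any change gave calls more often than the limit on adjusted p should allow, so these adjusted p-values may be too small. The 2 lactating arrays themselves left 1 residual degree of freedom per feature. The labels of these arrays do not say whether the lactating RNA was shared. The opposite side depended on the setting: in contrast with the reference against reference arrays 20 features were called, all on the casein side, and 10 of the 14 casein-side genes and 0 of the 15 opposite-side genes named above with a value on both of those arrays passed. Without array 1 the count was 40 features and without array 2 it was 13, and on the deposited values 187 features were called, of which 48.1% lay on the casein side against 71.3% after centring.

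**Figure D1:**
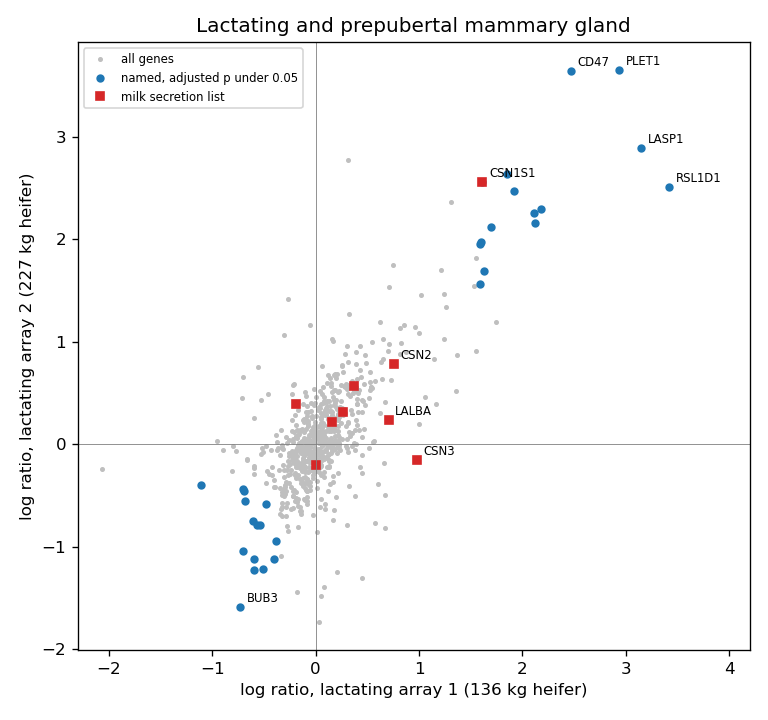
Each point is 1 gene, with its log ratio (base unstated) on lactating array 1 on the x axis and on lactating array 2 on the y axis; blue points are the 30 genes named by rule and red squares the milk secretion list, with CSN1S1, which is in both, drawn as a square. CSN1S1 lies at 1.61 and 2.56, and PLET1 at 2.93 and 3.65.

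The antigen presentation genes BOLA-DRB3, CD74 and BOLA and the epithelial adhesion gene EPCAM had their most positive deposited ratios in ileum among the tissues. The direction of these ratios was unsettled, and with the sign turned above and below trade places for every tissue. If these arrays shared the order of channels of the lactating arrays, positive would be the side of the reference. BOLA-DRB3 and CD74, the class II beta chain and the invariant chain, stood at 3.17 ± 0.21 (SD, 3 spots) and 2.41 ± 0.16 on the ileum array, 2.12 and 1.93 units above the next tissue. BOLA of class I stood at 1.62 there and EPCAM at 1.94. EP400, a chromatin remodeller, had the largest margin of any gene on either side in the 8 tissues, 3.05 units at a value of 3.37 ± 0.46, and the lysosomal membrane protein SCARB2 had 1.95 units. On reference against reference array 2, EP400 was at 1.33 and EPCAM at 1.51. On the negative side, C6H4orf19 stood 2.34 units below the next tissue at -2.66 ± 0.06, CLIC4 1.51, TPM4 1.27 and POSTN of the matrix 1.16 (at -1.52 ± 0.33), a ranking added after the data were seen. The chaperone HSP90B1 was at -1.16 and CAV1 at -0.82. The ileum array had 98 features at least 1 unit from 0, 37 positive and 61 negative, or 8.40% (95% Wilson interval 6.94% to 10.1%), and 32 features stood apart from all other tissues. Its share of exact 0 in the run of unannotated spots also differed from that of most tissue arrays, as given below.

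BOLA-DRB3 was also on the positive side in spleen (1.04) and lymph tissue (1.03), against 0.42 in mammary gland and 0.01 in liver. In lymph tissue the largest margins above the next tissue were those of NDRG1 (0.24), RBM47 (0.24), LIN52 (0.22) and YIPF5 (0.22). Those below it were TBK1 (0.28), LOC510377 (0.25), ARPC5 (0.25, SD over spots 0.64) and ASAH1 (0.24). All rankings below the next tissue in this paragraph were added after the data were seen. RBM47 was at -1.74 on reference against reference array 2. In spleen the largest margins above were those of HYAL1 (0.23), CSF3 (0.21), SLC1A5 (0.20) and COA4 (0.16). Below, spleen had GEM (0.29), MFSD1 (0.28), NUDT6 (0.28) and BET1 (0.28). Thymus had C6H4orf3 (0.50), CCT5 (0.35), AIMP1 (0.27) and SLC39A8 (0.26) above, and CXXC1 (0.45), RBMS2 (0.42), TUT7 (0.41) and CETN2 (0.37) below. Liver had ARPC5 (0.42, from 2 spots with an SD of 1.18), TRA2A (0.37), RAB3D (0.35) and EML6 (0.32) above. Below, it had C3 (0.71, SD over spots 2.15), ANXA8L1 (0.26, from 2 spots), PTPRC (0.22) and CSF1 (0.21). Adrenal tissue had SGCB (0.35), EIF5A (0.32, SD over spots 0.81), SLC37A3 (0.29) and UBE2D3 (0.27) above. Below, it had SF3B3 (1.15, SD over spots 0.59), SCARB2 (0.48), GIT2 (0.44, SD 0.53) and CRTC1 (0.43). CRTC1, at -0.34 in adrenal tissue, was at -1.14 on reference against reference array 2. Adipose tissue had ADAM9 (0.16, SD over spots 0.43), YIPF1 (0.15, SD 0.16), IMMT (0.15) and MCFD2 (0.15) above. Below, it had RARA (0.38, SD over spots 0.84), IRAK1 (0.28, SD 0.37), OGDH (0.25) and CIAO1 (0.24, SD 0.83). ADAM9 lay at -1.12 on reference against reference array 1 and, just under 1 unit from 0, at -0.997 on array 2. Of the hepatocyte genes, FGG was at 0.21, A2M at -0.27 and C3 at -1.10 (SD over spots 2.15) on the liver array.

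Prepubertal mammary gland was set apart by margins below 1 unit for every named gene. PRC1, a cytokinesis protein, lay 0.85 units above the next tissue, TMEM150A 0.81, RMDN1 0.80, the carnitine transporter family member SLC22A4 0.74 and the kinase MAPKAPK5 0.72. The margins of CLDND1 (0.68), ESYT1 (0.59), IDI1 of isoprenoid synthesis (0.58), RBM45 (0.55), TEAD3 (0.55), GNA14 (0.54), SIRT7 (0.53), FAM114A2 (0.51), BDH2 (0.50) and SNAPC3 (0.43) followed. The SD over 3 spots was larger than the margin for ESYT1 (0.82) and TEAD3 (0.66) and close to it for PRC1 (0.80), while it was 0.09 for CLDND1 and 0.21 for TMEM150A. Below the other tissues lay SLC28A1 by 0.35 units, EMC3 by 0.32, WTAP by 0.24, PRELID3B by 0.17 and MAPK1IP1L by 0.16, of which SLC28A1 (0.44), EMC3 (0.43) and PRELID3B (0.79) had SDs over spots larger than the margin. On reference against reference array 2, RMDN1 was at -1.45 and PRELID3B at -1.35. Among milk genes on that array, CSN1S1 was at -0.09, LALBA at 0.22, BTN1A1 at 0.39 and CSN2 at 0.42, and CSN2 was at 0.49 in ileum.

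2 features stood at least 1 unit above all 7 other tissues in mammary gland and 0 below, neither with a named gene, against 32 in ileum, 1 in adrenal tissue and 0 in the other tissues. The mammary array had 12 features at least 1 unit from 0, and the 6 arrays other than ileum and mammary gland had 2 to 5. The ileum and mammary arrays also differed from those 6 in the run of unannotated spots. It stood at exact 0 for 69.4% and 67.4% of its spots there, against 98.6% to 100% on the 6. A difference in how the arrays were processed can therefore not be told apart from a difference of tissue in these counts. The reference against reference arrays had 20 and 49, and of the tissue arrays the ileum exceeded both. On reference against reference array 2, which gave 49, the spots of a clone agreed little (mean rho 0.11, median SD over spots 0.293). That array is therefore a loose yardstick. With arrays scaled to the same MAD the reference against reference arrays had 20 and 12, and the ileum (28) and mammary (21) arrays exceeded both. Among gene lists, the stroma list had a median of -0.15 on the mammary array, at percentile 0.6 of random lists, with TNC and VCAN both at -0.32 and FBLN5 at 0.33. The milk fat list was at percentile 2.2 there, 98.1 in adipose tissue and 96.3 in liver, with medians of -0.04, 0.13 and 0.13, and GPAM at 0.22 and CD36 at 0.20 in adipose tissue. In ileum the secretory pathway list had a median of -0.42 (percentile 1.8), and the proliferation list one of -0.30 (percentile 3.2), with MCM7 at -0.69 and PCNA at -0.48. The milk secretion list lay at percentile 82.9 in mammary gland and 89.1 in ileum. These percentiles describe single arrays. Of the 40 computed, 6 lay below 5 or above 95, as did 8 of 40 lists drawn at random on the adipose array. That single simulation is a loose gauge of chance, since its lists and array differ from these. Whether the tally exceeds chance stays open.

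Lymph tissue and spleen had the most correlated arrays, with a Spearman rho of 0.74 and a Pearson r of 0.73 across 1154 features, against a median rho of 0.30 over the 28 pairs. All 8 arrays carry the same reference, so that rho also holds what sets that reference apart from the tissues. Lymph tissue with thymus (rho 0.54) and adipose tissue with spleen (0.51) came next. Mammary gland had its highest rho with lymph tissue (0.49) and thymus (0.44). Adrenal tissue had rho from -0.29 to 0.03 with the other tissues. With each feature's mean over the tissues subtracted, lymph tissue and spleen were again the highest pair (0.40), while mammary gland was at -0.09 with lymph tissue and 0.05 with thymus and had its highest value, 0.06, with adrenal tissue. Adipose with adrenal tissue (0.34) and adrenal tissue with liver (0.27) then ranked next, and lymph tissue with thymus was at 0.07 and spleen with thymus at -0.01. The tissue arrays correlated with the reference against reference arrays at rho from -0.12 to 0.27.

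**Figure D2:**
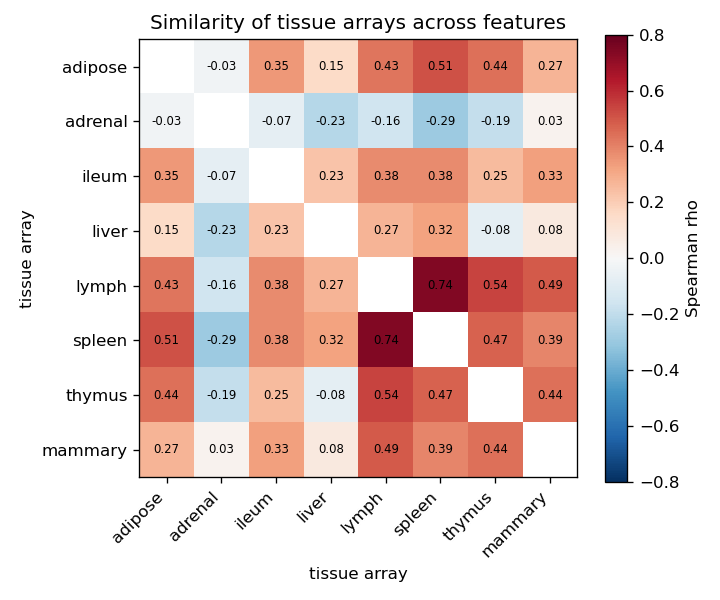
Spearman rho across 1154 features between each pair of the 8 tissue arrays, as colour and number, with the tissues on both axes. Lymph tissue and spleen have the highest value, 0.74, and adrenal tissue with spleen the lowest, -0.29.

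On the reference against reference arrays, 1.72% (95% Wilson interval 1.12% to 2.64%) and 4.32% (3.28% to 5.67%) of features lay at least 1 unit from 0. EIF4G1, a translation initiation factor, was the 1 feature that did so on the same side of both arrays, at -1.18 and -2.11. The 3 other features among the 4 largest means had no named gene, with means of -2.06, 1.58 and -1.37. Limma called 0 of 1123 features at an adjusted p of 0.05, and 49 at an unadjusted p under 0.05. The arrays correlated across features with a Spearman rho of 0.08, and on array 2 the spots of a clone agreed at a mean rho of only 0.11.

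No gene could be read from the comparison of postpubertal with prepubertal gland, since the spots of a clone did not agree on that array. 0 of 1161 features lay at least 1 unit from 0, which a 95% Wilson interval puts at up to 0.330%. Across features the array correlated with lactating array 1, which used a heifer of the same weight, at a Spearman rho of -0.01 and a Pearson r of -0.02, and with lactating array 2 at 0.01 and -0.01. Averaging spots that do not agree draws a feature toward 0 and lowers its correlation with other arrays. The count, its interval and the correlations therefore do not show that puberty left expression unchanged.

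**Figure D3:**
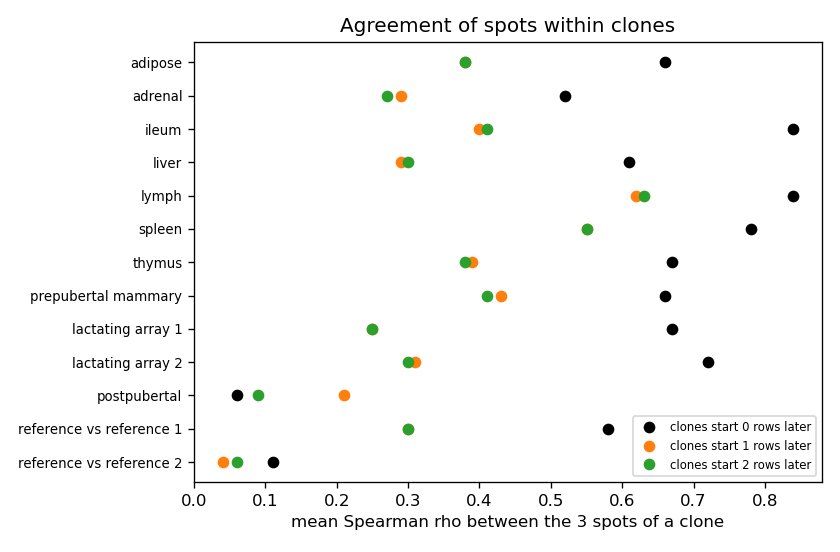
Mean Spearman rho between the 3 spots of a clone (x axis) on each of the 13 arrays (y axis), with clones taken to start at the stated row (black) or 1 (orange) or 2 (green) rows later. On the postpubertal array the value is 0.06 at the stated row and 0.21 for 1 row later, while on the other arrays the stated row has the highest value.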

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

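No paired analysis was possible because the labels number only the reference against reference arrays; the numbers of the lactating arrays were given here and pair nothing. Alternatives with the median of the spots, exact zeros kept, 1 spot being enough or the local trend removed were added after the data were seen; the others were fixed before the data were examined. Fold limits take the log ratios as base 2, which is open: 1.5-fold and 3-fold stand for 0.585 and 1.58 log units. The cause of a change was not tested unless stated. Signal over background was not used here, so its limits are unknown.

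On the lactating arrays, 136 called features became 51 with arrays scaled to the same MAD, 59 with the reference arrays sharing the spread, 20 in contrast with them, 287 after subtracting their mean, 70 with treat against 1.2-fold, 70 with exact zeros kept, and 13 to 40 with 1 array left out, where the lone array is assumed to vary like the reference arrays. The 37 features at least 1 unit from 0 on both became 23 after scaling, 88 at 1.5-fold and 21 at 3-fold. The milk secretion list lost its camera call on deposited values (adjusted p = 0.0566) and with 1 feature per gene (0.156). It also did so with an estimated correlation (0.907), a setting with 1 residual degree of freedom that could hardly call any list. After subtracting the reference mean, EPCAM (adjusted p = 0.0055, limma) and SAR1A (0.0166) were called on the other side of 0. That setting leaves the noise of the reference arrays out of the spread, and EPCAM was at 1.51 on reference against reference array 2. Among the named genes and list members on these arrays, 162 values over all alternatives lost a call, 14 gained one and 2 reversed.

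The percent of reference against reference values at least 1 unit from 0, 3.01, became 1.39 after scaling, 0.623 after subtracting their mean (which lowers it by construction), 2.12 with exact zeros kept, 3.81 with 1 spot being enough, 8.32 at 1.5-fold, 0.697 at 3-fold and 1.72 to 4.32 with 1 array left out. The 1 feature on the same side of both became 2 on deposited values and with the median of the spots, 3 with 1 spot being enough, 5 at 1.5-fold, and 0 at 3-fold or after subtracting the mean.

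Counts for adipose, adrenal, liver, lymph, spleen, thymus and mammary arrays, in that order, were 2, 4, 5, 4, 3, 3 and 12. They became 13, 9, 9, 24, 25, 27 and 52 at 1.5-fold, 0, 1, 0, 0, 0, 1 and 1 at 3-fold, and 13, 15, 12, 12, 16, 19 and 20 after subtracting the reference mean. Scaling gave 13, 7, 9 and 21 for adipose, adrenal, liver and mammary arrays. Features with a value on all arrays gave 1, 0, 3, 2, 1 and 0 for the first 6. The median of the spots gave 1 for adipose and 5 for thymus. The ileum count of 98 became 28 after scaling, 224 at 1.5-fold and 24 at 3-fold. The postpubertal count of 0 became 3 after scaling, 16 after subtracting the reference mean and 13 at 1.5-fold. The 2 features apart in mammary gland became 4 after scaling, 18 at 1.5-fold and 0 at 3-fold, and kept within 1.5 times with each other tissue left out. Removing the local trend moved the rho of lymph tissue and spleen from 0.74 to 0.54 and the median over pairs from 0.30 to 0.21.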

Other observations

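The tests with the local median were set before their result was seen, and the other tests were chosen only after the result was seen. On the ileum array TAP1, the peptide transporter of class I presentation, stood at 0.83 beside BOLA at 1.62, and the leukocyte genes RAC2, PTPRC and LCP1 stood at 0.85, 0.50 and 0.10, in lists too short to be tested. The amino acid transporters SLC1A5 (-0.73) and SLC3A2 (-0.63) and the chaperonin HSPD1 (-0.75) stood on the other side. On the lactating arrays the same class I gene BOLA was on the opposite side (-0.66), whereas TAP1 was at 0.40.

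The spots of a clone did not agree on the postpubertal array. The tables argue against an array with no clone-specific signal, since a mean spot agreement of 0.21 appeared with clones starting 1 row later, against 0.06 at the stated row, whereas on each other array the value was lower 1 row later than at the stated row. A candidate explanation is that its rows stand 1 place, or 1 plus a multiple of 3, off the clone table, which needs that value of 0.21. How many rows is open: the largest row correlation with a lactating array was 0.049 in size over shifts of up to 12 rows. The biological difference between the stages stays untested.

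Clone ratios on reference against reference array 1 were repeatable over spots, though both channels held RNA of 1 cell line. A dye effect of each clone shared by both arrays is argued against by their Spearman rho of 0.08, where spot agreement would allow up to 0.47. A trend along the rows is argued against as the whole cause, since the spot agreement stayed at 0.55 after the median of 15 neighbouring clones on either side was subtracted. What made them repeatable on that array stays open. The design offers no biological explanation here, and none was tested.

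Lymph tissue and spleen had the most correlated arrays of the tissues, all set against 1 reference. A trend along the rows shared by the arrays does not account for the whole of it, since rho stayed at 0.54 after the local median was subtracted, although it had been 0.74, so part of the resemblance may come from that trend. That lymphoid organs share ratios as a class stays open: 2 other pairs ranked above spleen with thymus, but the highest did so by a rho of 0.05, with an interval over 1000 resamplings of features from -0.01 to 0.10. With each feature's mean subtracted, spleen with thymus was at -0.01, below adipose with adrenal tissue at 0.34, but subtracting a mean of the same arrays itself moves the rho of pairs. A likeness of lymph tissue and spleen alone stays open and untested.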
